A study of Mus musculus with 2 samples.

How the data were processed

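DNase-seq, which maps stretches of chromatin open to cutting by the enzyme DNase I, was measured in the right cerebral cortex of female adult mice aged 18 to 20 months. The mice were first-generation hybrids of the C57BL/6J and CAST/EiJ strains. The labels give 2 biological replicates of this tissue in 1 group, with no treatment and no control, so no comparison between groups was made. The labels mark the replicates as separate biosamples but give the same donor identifier for both. Nothing in the sources used here says whether they came from separate animals, and the spread between them may be partly technical.

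The deposited files give mm10 coordinates per library, per the deposited descriptions. Each library has 2 peak lists, a list of footprints and a list of intervals with a false discovery rate. The peak caller, its version and the aligner are not given in the sources used here. The value of each peak is a signal that the authors deposited, and how it was normalized is not given in the sources used here. In each library all peak values were whole multiples of 1 step within a tolerance of 0.05 steps. The step was 0.00497 in replicate 1 and 0.00892 in replicate 2. If 1 step is 1 read scaled to reads per M, the libraries held 201 M and 112 M reads (M for mega), a ratio of 1.79. That depth is inferred from the values and is not stated by the files. On that reading the median peak of the shorter list rested on 145 reads in replicate 1 (exact 95% Poisson interval 122 to 171) and 112 in replicate 2 (92.2 to 135). These intervals cover counting error only. The interval lists carry an FDR (q-value) per interval, per the deposited descriptions, and the files list only intervals below 0.05. The footprint lists carry the same FDR p-value threshold of 0.01 in all rows, as the authors deposited it.

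The plan made before the data were examined took as the main peak list the one with the smaller median region width. Both lists of each library had a median width of 200 bp, so the tie was broken by the smaller mean width, 205 bp against 207 bp in replicate 1 and 204 bp against 210 bp in replicate 2. The list so chosen is the shorter of the pair, and all of its peaks touched an interval with an FDR of 0.001 or less. The longer list was used as an alternative.

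Genes, transcription start sites and exons came from GENCODE M21 and the genome sequence from GRCm38.p6, the assembly that mm10 names. The text descriptions of the samples hold no measurement and were not used as data. No chromosome held a peak beyond the end of its reference sequence. Chromosomes 1 to 19, X and Y were used, with 21938 protein-coding genes and 101639 of their start sites. A promoter was the 500 bp on either side of any annotated start site of a gene, and its value was that of the strongest peak overlapping it. A peak near start sites of neighbouring genes counted for each of them. Regions of both libraries were merged, and a merged region holding a peak of each library was called shared. Overlap needed at least 1 bp. Distal regions were shared regions with no base within 500 bp of a start site of any gene, and each went to the nearest protein-coding start site within 100 kb. Peaks were placed by their midpoint as promoter, exon, intron or intergenic, in that order. Expected overlaps came from 100 circular shifts of a list along its chromosomes and, for footprints, 100 random placements within shared regions.

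The 21 gene lists and 19 consensus motifs were fixed before the data were examined. Members with a promoter peak in both replicates were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05. Medians of lists were placed among those of 10000 random lists of the same size. A pseudocount of 0.1 was added before log2 where genes without a peak entered. Genes are not replicates, so these tests and percentiles describe the tissue's lists and not a population of mice. Differences between the libraries were centred on the median over all genes with a promoter peak in both and needed at least 3 such members per list. Motif occurrences on either strand of shared regions were counted as occupied when wholly inside a footprint, and compared with the same string reversed without complementing, by exact (Clopper-Pearson) 95% intervals per replicate. A motif was called where the intervals did not overlap in both replicates. Shares are given with exact 95% binomial intervals or as mean ± SD over the 2 replicates.

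The named genes were set by a rule made before the data were examined. It takes the 3 members of each list with the highest mean log2 promoter value and up to 2 members without a promoter peak. It adds the 5 genes with the most distal shared regions, the 5 strongest shared regions, and the 5 genes with the largest promoter difference in each direction. Some genes that the rule takes are not reported.

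Alternatives varied the peak list, the strength threshold, the overlap, the promoter window, the assignment distance, the replicates used, the centring, the scale, the footprints and motifs counted, and the background genes. Start sites of basic transcripts, a pseudocount of 1, and random genes matched on promoter CpG content and number of start sites, or on the bases nearest to the gene, were added after the data had been seen. Each matched member was drawn from the 200 most similar genes, or the 40 most similar where only X genes were drawn. The steps were tested on simulated data. A simulated overlap of 76.3% over 79391 peaks was recovered as 76.3%. Of 200 simulated lists of 15 genes with a 95% promoter share, 94.0% were called, against 0% of 200 random lists. Smaller differences from other genes, and shorter lists, were not simulated. The 94.0% therefore does not apply to them. The random lists were drawn from all protein-coding genes. That 0% therefore does not cover lists that differ from other genes in CpG content or number of start sites. All 950 planted motif copies were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and minimap2 aligned peak sequences for a test in the closing section.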

Results

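Open chromatin was mapped by DNase-seq in the right cerebral cortex of female hybrid mice aged 18 to 20 months, in 2 biological replicates of 1 group. The series has no second condition, so the questions are which genes and regions were accessible in this tissue and how far the replicates differed. Peak values are the authors' deposited signal. The inferred depth was 201 M reads (M for mega) for replicate 1 and 112 M for replicate 2, as read from the steps of the values. Values differ in level between the libraries, so the SD of a mean value includes that shift.

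Replicate 1 had 86601 accessible regions and replicate 2 had 88482, a mean of 87541.5 ± 1330 (SD, n = 2). They covered 17.6 Mb (0.663% of the genome) and 17.8 Mb (0.673%). Among autosomes, chromosome 11 was the densest with 48.0 ± 0.798 regions per Mb and chromosome 3 the sparsest on average with 29.3 ± 0.995. In replicate 2 chromosome 14 was slightly sparser than chromosome 3 (29.91 against 30.01). The X chromosome held 13.4 ± 1.21 regions per Mb, below all autosomes in both replicates. Its median peak value was 0.522 in replicate 1, against 0.676 on chromosome 3, the lowest autosome, and 0.669 in replicate 2, against 0.892 there. The Y chromosome, which female mice lack, held 37 peaks in replicate 1 and 7 in replicate 2.

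**Figure D1:**
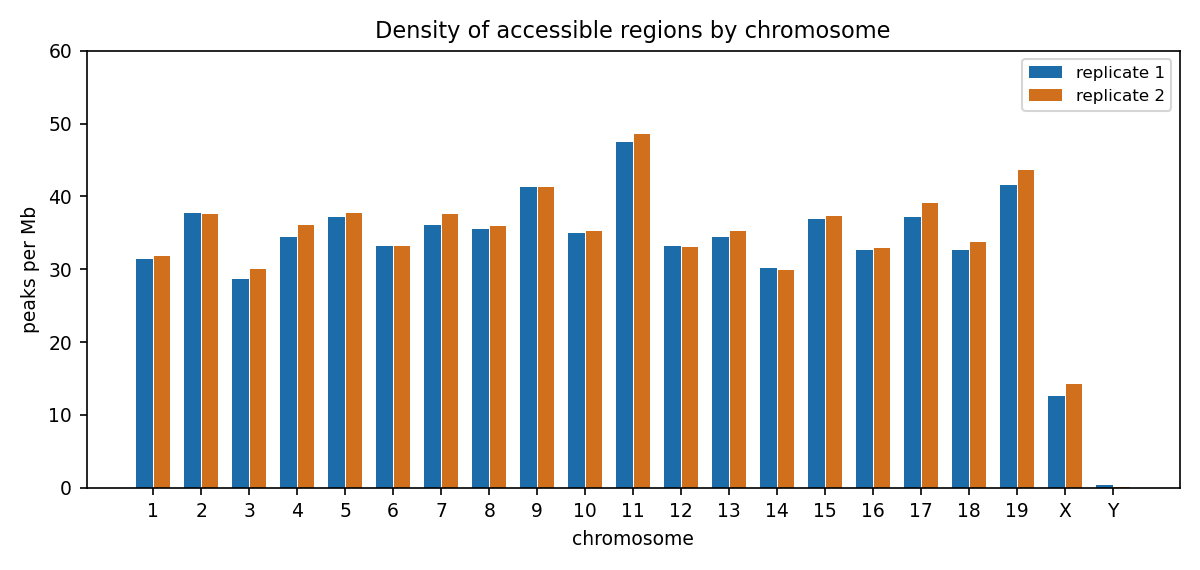
Accessible regions per Mb of sequenced bases (vertical axis) on each chromosome (horizontal axis), with 1 bar per replicate. Chromosome 11 stands highest at 48.0 on average, and the X chromosome at 13.4 lies below all autosomes.

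Promoters were the class most enriched for accessible regions. They took 24.7 ± 0.513% of the peaks (SD, n = 2), 7.59 ± 0.158 times their 3.26% share of the genome. Exons outside promoters held 5.12 ± 0.278% of the peaks, 1.40 ± 0.0759 times their share. Introns held the largest number, 37.8 ± 0.945%, close to their share of the genome at 0.947 ± 0.0237 times. Intergenic sequence held 32.4 ± 0.154%, or 0.609 ± 0.00289 times its share. The fold of promoters depended on the window and was 3.26 with 2000 bp on either side.

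The replicates had most regions in common. Of the regions of replicate 1, 77.0% overlapped a region of replicate 2, and 75.6% did so in the other direction, against 1.37% and 1.35% for shifted lists. Merging gave 105529 regions, of which 64789 (61.4%) were shared, 19554 were found only in replicate 1 and 21186 only in replicate 2. Regions in the highest quartile of values overlapped in 98.2% and 97.8% of cases and those in the lowest quartile in 52.0% and 46.0%. Regions found in a single replicate were weaker, with a median value of 0.487 against 0.845 for shared ones in replicate 1 and 0.597 against 1.22 in replicate 2. Of those single-replicate regions, 60.8% and 56.5% were in the longer list of the other library.

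Across shared regions the log2 peak values of the replicates had a Pearson correlation of 0.870 and a Spearman correlation of 0.842, and regions are not independent replicates. Values in replicate 2 were 1.36-fold higher at the median, and 84.5% of shared regions were higher in it. The log2 difference had an SD of 0.50, against a median of 0.17 from counting error at the inferred depth. Shared promoter regions differed by a median log2 of -0.51 (replicate 1 minus replicate 2) and distal ones by -0.40.

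Of 21938 protein-coding genes, 12692 had a promoter peak in both replicates (57.9%, exact 95% interval 57.2% to 58.5%). A further 339 had one only in replicate 1 and 540 only in replicate 2. The remaining 8367 genes (38.1%) had none in either list.

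Promoters of general neuronal, activity-regulated and housekeeping genes were accessible more often than those of all other genes. None of these calls was kept against random genes matched on promoter CpG content and number of start sites. The mean matched shares were 79.4%, 83.6% and 88.9%, in that order. Of 18 pan-neuronal genes 17 had a promoter peak in both replicates, 94.4% against 57.8% of other genes (Fisher's exact test, adjusted p = 0.00314). By the mean of the replicates the strongest were Syt1, a calcium sensor of synaptic vesicle release (3.51 ± 0.363, SD, n = 2), Tubb3, a neuronal tubulin (3.25 ± 0.684), and Grin1, a subunit of NMDA glutamate receptors (3.13 ± 0.976). In replicate 2 Grin1 (3.82) and Tubb3 (3.74) lay above Syt1 (3.25). All 14 activity-regulated genes, which neurons induce on stimulation, had a promoter peak (exact test, adjusted p = 0.00204), led by Arc (5.27 ± 1.42), Junb (4.94 ± 1.22) and Egr1 (4.65 ± 1.24), whose strongest promoter peak lay at a different position in each replicate. All 15 housekeeping genes had one too (exact test, adjusted p = 0.00135), including Rplp0 (6.69 ± 0.659), Rpl13a (6.16 ± 0.374) and Actb (5.64 ± 0.451).

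Markers of neuron classes did not pass the test. Of 17 excitatory cortical markers 13 had a promoter peak in both replicates (76.5%, exact test, adjusted p = 0.178), and this list passed without replicate 2 (adjusted p = 0.0263). Its highest values were at Tle4, a corepressor of deep-layer neurons (9.22 ± 1.47), Camk2a, a kinase of excitatory synapses (3.26 ± 0.976), and Nrgn, a postsynaptic calmodulin-binding protein (2.92 ± 0.221). Fezf2, a regulator of subcortical projection neurons, had none. Of 17 inhibitory markers 7 had one (41.2%, exact test, adjusted p = 0.255), with Maf at 1.34 ± 0.0228 and Adarb2 at 1.06 ± 0.304. Gad2 and Slc32a1, which serve synthesis and vesicular loading of GABA, had none in the shorter list of either replicate. Of the other inhibitory markers 3 had a peak only in replicate 1 and 3 only in replicate 2. Striatal markers had 5 of 10 (exact test, adjusted p = 0.751), and cerebellar markers, with 3 of 10, did not pass either.

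Among glial lists the shares differed. Astrocyte genes had promoter peaks at 11 of 16, with Glul, which makes glutamine, at 3.36 ± 1.20, Aldoc at 2.06 ± 0.909 and the glutamate transporter Slc1a2 at 1.62 ± 0.344, and none at Aqp4 or Fgfr3. Oligodendrocyte genes had 6 of 16, with the transcription factor Olig1 at 1.68 ± 0.237, the myelin protein gene Mbp at 1.22 ± 0.408 and Cnp at 0.979 ± 0.506, and none at Mag or Aspa. Their precursors had 5 of 10, including Tnr (2.37 ± 0.439), Pdgfra (1.59 ± 0.582) and Vcan (1.15 ± 0.510). None of these 3 lists passed the exact test (adjusted p = 0.502 for astrocytes, 0.168 for oligodendrocytes and 0.751 for precursors). The strongest promoter peaks of Slc1a2 and Tnr lay at different start sites in the 2 replicates. Microglial genes were accessible less often than all other genes, at 5 of 18 (27.8%, Fisher's exact test, adjusted p = 0.0280). Random genes matched on promoter CpG content and number of start sites had a mean share of 27.7%, so microglial genes did not stand apart from these. Among the microglial genes with a peak were Aif1 (1.06 ± 0.334) and Irf8 (1.01 ± 0.00448), and the complement genes C1qa and C1qb had no promoter peak. Interferon and age-related glial genes had 5 of 20 (exact test, adjusted p = 0.0106), among them H2-D1 (4.03 ± 2.40) and Cdkn1a (1.72 ± 0.373), and none at C3 or Axl. Their call was not kept against genes matched in the same way (25.0% against a mean of 40.8%).

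Vascular, choroid plexus and non-neural lists were accessible less often than all other genes. Against genes matched on promoter CpG content and number of start sites, only the endothelial, striated muscle, Hox and vomeronasal receptor calls were kept. Endothelial genes had 3 of 15 (exact test, adjusted p = 0.00827), with the glucose transporter Slc2a1 at 2.08 ± 0.385, and mural cell genes had 2 of 10 (adjusted p = 0.0327). Choroid plexus and ependymal genes also had 2 of 10 (exact test, adjusted p = 0.0327), both of them genes of motile cilia, Enkur (4.22 ± 1.39) and Foxj1 (4.09 ± 1.52). The strongest Enkur peak lay wholly upstream of the annotated gene in both replicates, and whether it belongs to a neighbouring gene was not tested. None of 15 hepatocyte genes had a promoter peak in either replicate (exact test, adjusted p = 1.64e-05). Striated muscle genes had 1 of 17 (exact test, adjusted p = 5.30e-05), which was Tnnt2, and erythroid genes 1 of 11 (adjusted p = 0.00314), Epor at 1.96 ± 0.395. Lymphocyte genes had 2 of 10 (exact test, adjusted p = 0.0327), Lck and Pax5. Of 39 Hox genes, which pattern the body axis behind the forebrain, 2 had one (5.13%, exact test, adjusted p = 3.40e-11), Hoxa7 and Hoxd1. Of 330 vomeronasal receptor genes 2 had one (0.606%, exact test, adjusted p = 1.08e-119), Vmn1r4 and Vmn1r20. How uniquely reads map to these receptor genes, and strain variants in them, were not tested, so their low share may not reflect accessibility alone.

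Some calls depended on the settings. With the longer peak list excitatory markers passed the exact test (adjusted p = 0.0115), and mural cell (0.0629) and interferon genes (0.300) did not. With promoter windows of 2000 bp excitatory markers passed the exact test (adjusted p = 0.0396), and mural cell (0.243) and choroid plexus genes (0.0713) did not. With windows of 100 bp neither of the latter lists passed the exact test (adjusted p = 0.0696 for each). With the stronger 50% of peaks inhibitory (adjusted p = 0.00228) and oligodendrocyte genes (0.00342) lay below other genes by the exact test, and choroid plexus genes (0.0677) did not pass. Against random genes matched on promoter CpG content and number of start sites, a comparison added after the data had been seen, 4 of the 14 calls were kept and 10 were lost. Endothelial genes (adjusted p = 0.0437), striated muscle (0.0252), vomeronasal receptors (0.0252) and Hox genes (0.00420) stayed low among 10000 random matched lists (two-sided share of lists, not an exact test). In the same comparison pan-neuronal (0.203), activity-regulated (0.225), housekeeping (0.368) and microglial genes (1) did not stand apart. The other lost calls were of mural (0.262), choroid plexus (0.133), interferon (0.160), hepatocyte (0.189), erythroid (0.338) and lymphocyte genes (0.217). Inhibitory markers lay low among the random matched lists, at 41.2% against a mean of 75.6% (adjusted p = 0.00840, not an exact test). In each replicate taken alone 58.8% of inhibitory markers had a promoter peak. Their difference from all other genes, -16.7 points with both, was -1.49 points without replicate 1, -0.576 points without replicate 2 and 20.0 points with the longer peak list, and the matched comparison was not run under these settings.

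**Figure D2:**
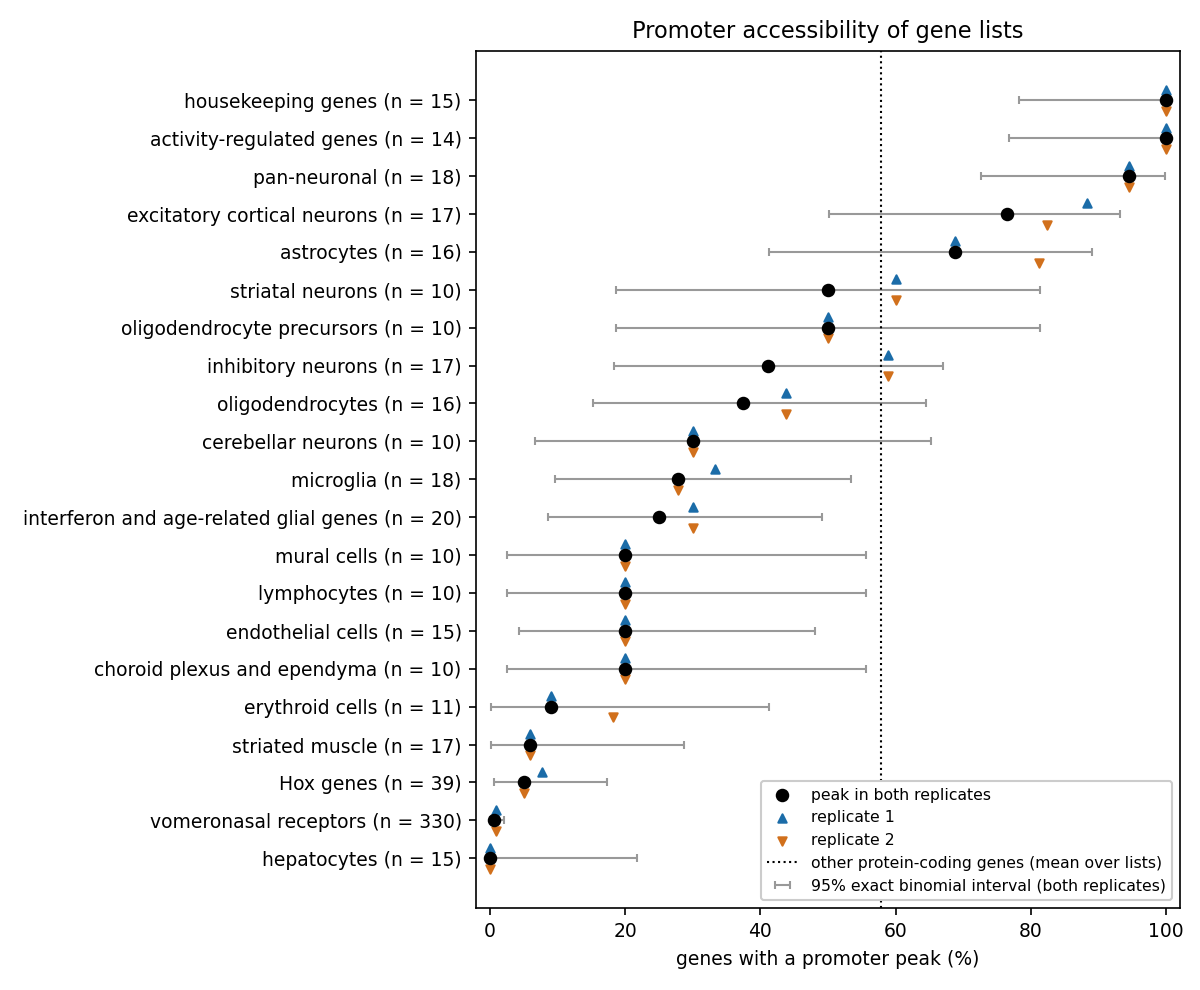
Share of genes with a promoter peak (horizontal axis, percent) in each gene list (vertical axis, n genes), as black points for peaks in both replicates with exact 95% binomial intervals and coloured triangles for each replicate alone. Housekeeping and activity-regulated genes stand at 100%, pan-neuronal genes at 94.4%, and hepatocyte genes at 0%, around a dotted line for other protein-coding genes.

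Distal accessible regions were also counted. Of the 64789 shared regions 46200 (71.3%) were distal, and 35520 of these lay within 100 kb of a protein-coding start site, a median of 1 per gene. Pan-neuronal genes had a median of 5 and lay at the 100th percentile of random lists, activity-regulated genes had 4 (percentile 99.98), excitatory markers 4 (99.99) and oligodendrocyte precursor markers 2.5 (97.76). Tnr, a matrix glycoprotein gene, had 20 such regions, Syt1 and Slc1a2 had 10 each, and Mbp had 9. Oligodendrocyte genes had a median of 2 (97.14) and astrocyte genes 1.5 (90.5), inside the central 95% of random lists. Against genes matched on the bases nearest to them, pan-neuronal (99.85) and activity-regulated genes (99.99) stayed outside that range, and excitatory (89.3) and precursor markers (85.9) did not. Without replicate 2 astrocyte (99.9) and oligodendrocyte genes (98.9) lay above the range and precursor markers (96.6) inside it, and without replicate 1 oligodendrocyte genes lay above it (98.2). Vomeronasal receptor genes had a median of 0 (percentile 7.32) and lay below the range without replicate 2 (0.145), without replicate 1 (below all random lists) and against matched genes (0.04), but inside it with the stronger 50% of peaks (50), windows of 2000 bp (42.4) and assignment within 50 kb (17.8). A median of 0 is the lowest possible, so where many random lists tie with it the percentile cannot fall below the range. These 3 settings therefore do not show that a depletion was lost. Under the main settings 307 of the 330 receptor genes had no distal shared region. Their mean was 0.1, against 1.62 over all protein-coding genes. Precursor markers also lay inside the range with the stronger 50% of peaks (38.0), windows of 2000 bp (92.2) and assignment within 50 kb (72.5). The longer peak list put 8 lists outside the range instead of 4, adding astrocyte (99.1), oligodendrocyte (98.6), vomeronasal receptor (below all random lists) and Hox genes (2.46), and windows of 2000 bp put oligodendrocyte genes above it (98.9).

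Among the genes with the most distal shared regions, Kalrn, a guanine nucleotide exchange factor of dendritic spines, had 35 on chromosome 16 (33969073 to 34573532). Pde4d, a phosphodiesterase gene on chromosome 13, had 34. Kcnma1, a potassium channel gene on chromosome 14, and Nav2 on chromosome 7 had 33 each. Camk2a (chromosome 18, 60925618 to 60988152, plus strand) had 7, and its strongest promoter peak lay at 60925461 to 60925680 in replicate 1, which had another at 60925129 to 60925400.

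**Figure D3:**
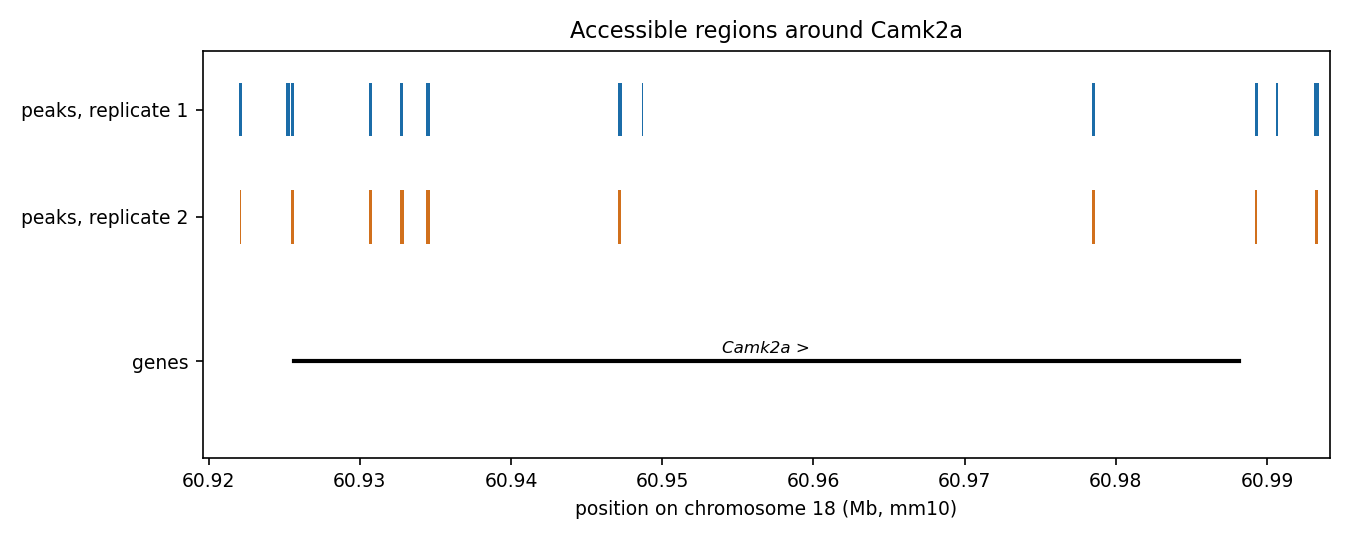
Accessible regions of each replicate (coloured blocks drawn to scale) around Camk2a (black line, arrow for the plus strand) along chromosome 18 in Mb of mm10. Replicate 1 had 12 regions in the window and replicate 2 had 9.

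The replicates were also compared by gene list, as 1 library against 1, which allows no test. Of 13 lists with at least 3 members accessible in both, 2 lay outside the central 95% of random lists, and 0.65 would do so by chance. Striatal genes were relatively higher in replicate 2, with a median centred log2 difference of -0.52 (replicate 1 minus replicate 2, percentile 0.35). This list had 5 members, of which 3 were higher in replicate 2 and 2 in replicate 1. Ppp1r1b, higher in replicate 1, had its strongest promoter peak at a different position in each library, so its value compares different regions. The dopamine receptor gene Drd1 was 2.22-fold and the signalling regulator Rgs9 2.23-fold higher in replicate 2 before centring. Interferon and age-related glial genes had a median of -0.45 (percentile 0.81), with H2-D1, a major histocompatibility gene, at a centred log2 difference of -0.80. Housekeeping genes sat just inside the limit with a median of 0.21 (percentile 97.4). Among single genes the promoter values of Rprd2, Hbq1a and Kif22 were the highest in replicate 2 relative to replicate 1, with centred log2 differences of -1.84, -1.73 and -1.71. Coro2b, Phldb1 and Parvb were highest in replicate 1 relative to replicate 2, with centred log2 differences of 3.66, 1.72 and 1.60. The strongest promoter peak lay at a different position in each library for Rprd2, Kif22, Coro2b, Phldb1 and Parvb, so those values compare different regions.

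By the mean of the 2 replicates, the strongest shared region was in a ribosomal RNA gene on chromosome 17 (39846781 to 39846920), with a value of 44.6 ± 23.2 (SD, n = 2). The second, on the X chromosome (170009841 to 170010180), was in the promoter of Gm21887, 119 bp from its start site, with 28.2 in replicate 1 and 31.8 in replicate 2. The third was in an exon of Lars2 on chromosome 9 (123461881 to 123462140, 24.4 ± 15.3). The others were intergenic, on chromosome 3 (5860361 to 5860530, 24.3 ± 12.6) and on the X chromosome 35530 bp from Pak3 (143482981 to 143483140, 21.3 ± 5.51). The order differed between replicates. In replicate 1 the Gm21887 region (28.24) lay above the ribosomal RNA region (28.15). In replicate 2 the Lars2 (35.2) and chromosome 3 (33.2) regions lay above the Gm21887 region. Regions of repeated sequence were not filtered out here, so these values may not measure accessibility alone.

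Footprints are short protected stretches within accessible chromatin. Replicate 1 had 307092 with a median width of 9 bp and replicate 2 had 279769 with a median of 10 bp. Of these 41.4% and 43.6% overlapped a footprint of the other replicate. Inside shared regions the shares were 54.8% and 53.4%, against 28.9% and 29.2% when footprints were placed at random. A footprint lay in 94.4% of shared regions in replicate 1 and 91.8% in replicate 2.

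Of 19 motifs, 9 lay wholly inside footprints more often than their reversed strings in both replicates. Reversing keeps the bases of a motif but not their order, and the reversed CRE and ETS strings hold no CpG. Whether reversed strings lay in other kinds of regions than the motifs was not tested. CTCF, which organises chromatin loops, had the highest share, with 81.4 ± 9.96% of 3832 occurrences (SD, n = 2) against 0 of 12 reversed ones. NRF1 had 71.3 ± 3.40% against 9.76 ± 6.90%, CRE, the site of CREB proteins, 67.6 ± 5.21% against 6.77 ± 3.50%, and EGR 54.9 ± 5.16% against 9.82 ± 2.98%. SP/KLF sites had 49.2 ± 13.1%, but their reversed strings, which are also rich in G, had 31.6 ± 8.32%. RFX had 36.5 ± 2.21% against 1.28 ± 1.81%, ETS 19.6 ± 3.84% against 7.25 ± 0.733% and the neuronal bHLH motif 18.9 ± 0.842% against 2.22% reversed. AP-1 sites were the most numerous at 7986, with 9.17 ± 1.51% inside footprints against 3.18 ± 0.750% reversed. MEF2 sites had 9.95% against 0.962% in replicate 1 and 4.64% against 1.92% in replicate 2, and passed without replicate 2 but not with both. In distal shared regions alone 7 motifs passed, and NRF1 and ETS did not. Counting occurrences with any base in a footprint 11 motifs passed, MEF2 and ZNF143 among them. Among control motifs of other tissues, GATA had 1.04 ± 0.0979% against 1.29 ± 0.364% reversed, HNF4 had 3.90 ± 0.918% against 0.510 ± 0.722% reversed with overlapping intervals, and HNF1 had no occurrence. NFI (43.1 ± 13.7% of 36 sites), YY1 and ZNF143 counted wholly inside footprints could not be separated from their few reversed occurrences, SOX (2.30 ± 0.362%) and T-box (6.62 ± 1.08%) overlapped theirs, and none of 24 REST sites, 16 bp long, lay wholly in a footprint.

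**Figure D4:**
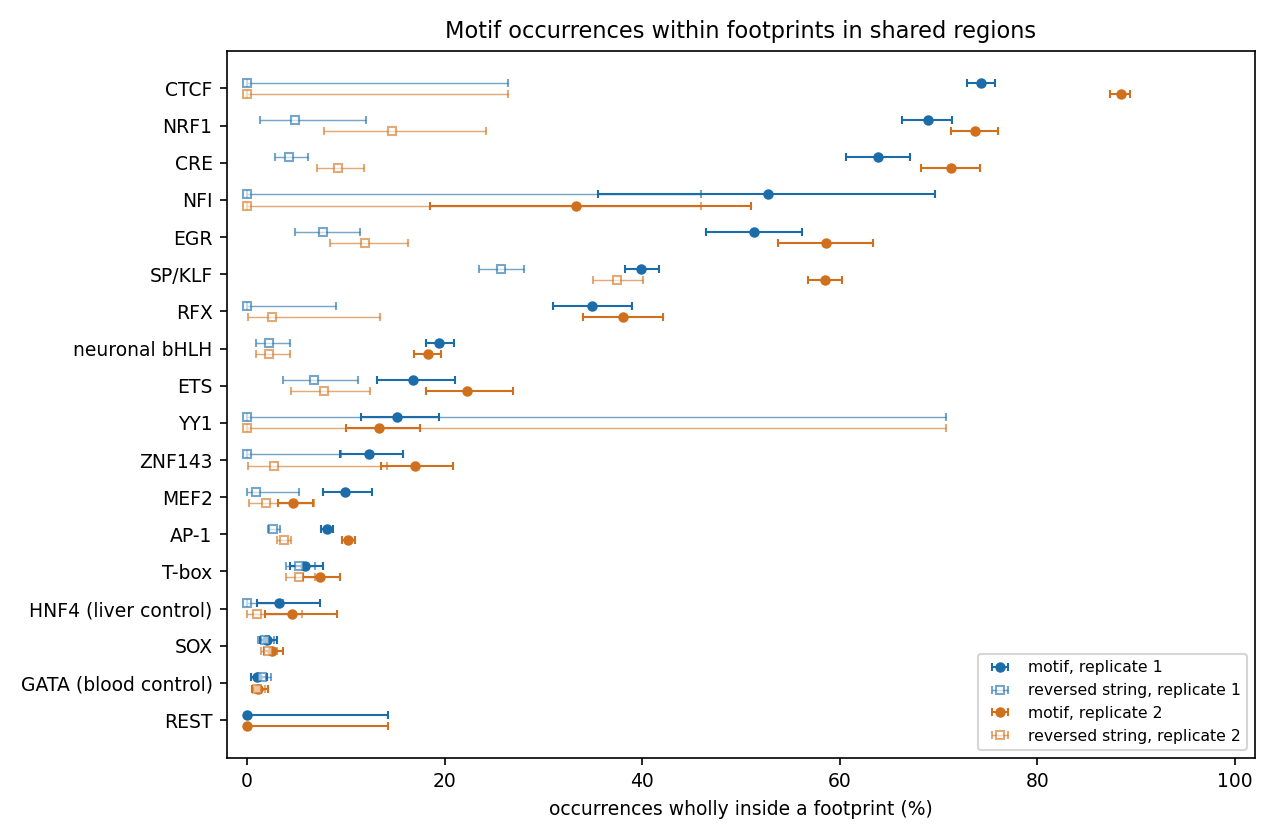
Share of motif occurrences wholly inside a footprint (horizontal axis, percent) for each motif (vertical axis), with filled points for the motif and open squares for its reversed string, coloured by replicate, with exact 95% binomial intervals. CTCF has the highest share at 81.4% on average, and the GATA motif lies at 1.04%.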

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

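The matched-gene, basic-transcript and pseudocount settings were chosen after the data had been seen and the others before. Of 210 list shares recomputed under alternatives, 183 kept their direction and their side of the threshold, 16 lost the call in the same direction, 6 gained it and 5 turned direction, of which microglia also lost its call. Except where fewer regions or another window enter by construction, the cause was not tested. With the longer peak list there were 142542 regions per replicate, 74.3% overlap, a correlation of 0.885, 62.4% of genes with an accessible promoter, 5.85-fold promoter enrichment and 8 gene lists outside the central range of distal counts, and the differences of inhibitory (20.0 points) and striatal genes (7.61 points) turned positive. With the stronger 50% of the peaks there were 43548 regions, 79.5% overlap, a correlation of 0.826, 51.6% of genes and 10.8-fold enrichment. Requiring overlap of 50% of both regions gave 63.3% for peaks and 28.5% for footprints, and footprints inside shared regions overlapped at 54.1%. Promoter windows of 2000 bp gave 61.7% of genes and 3.26-fold enrichment, windows of 100 bp gave 53.6% of genes, and basic transcripts gave 55.8%. Linear values gave a correlation of 0.897. Leaving out a replicate gave 59.4% to 60.3% of genes, and a striatal difference of -0.316 to 0.601 points. Genes matched on CpG content and start sites left 5 lists past the threshold, with astrocytes at -3.52 and microglia at 0.121 points. Overlap and agreement need both replicates, so leaving out either gave no value for them. No paired analysis was possible because the series has 1 group. What depth limits was not tested: overlap was 98.2% in the highest quartile of values and 52.0% in the lowest in replicate 1, and 97.8% and 46.0% in replicate 2.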

Other observations

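The predictions for the tests in this part were written before the tests were run, on patterns already seen in the data, and the comparison with the SD in the test of striatal tissue was added after its result was seen, as was the matching of the genes that escape silencing. Promoters on the X chromosome were less accessible than autosomal ones. In replicate 1 44.5% of X genes had a promoter peak against 60.6% of autosomal genes, and in replicate 2 the shares were 44.5% and 61.6%. Among the 403 X genes with a peak in both replicates the median value was 1.30 in replicate 1 and 1.67 in replicate 2, against 2.24 and 3.28 for 12289 autosomal genes.

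A candidate explanation for the lower values is the silencing of 1 X chromosome in female cells, and the lower share of X genes with a peak was not tested. Base composition alone did not account for the lower values, since against autosomal promoters matched on GC and CpG content the X median was still 0.655 times as high in replicate 1 and 0.560 times in replicate 2, at percentile 0.01 of random sets in both, the smallest they can give. The 6 genes known to escape silencing that were set beforehand, such as Kdm6a (8.62 and 10.6) and Ddx3x (2.56 and 3.46), had medians of 3.41 and 5.20, at percentile 99.99 of random X promoters and also of X promoters matched on GC and CpG content, the highest that the draws can give. Among matched autosomal promoters they lay inside the central 95% but high, at percentiles 90.8 and 96.6, so strong promoters of these genes may add to their excess, which does not measure escape. Silencing therefore stays a hypothesis, and differences in mappability or strain variants on the X chromosome were not tested.

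The relatively higher striatal promoters of replicate 2 may come from the dissection or from the library. Against promoters matched on peak strength and GC content the list stayed at percentile 1.32, which argues against a trend with these as the whole cause. More striatal tissue would raise the distal regions of the same genes, and their 20 shared regions had a median centred log2 difference of 0.08, at percentile 82.1 of random sets. That met the bound set beforehand against a larger striatal part. Of these regions 11 were higher in replicate 1 and 9 in replicate 2. Their SD of 0.67 exceeds the distance from their median to the promoter median of -0.52. That SD describes single regions and not the error of their median, so it cannot overrule the bound. As a set, these distal regions showed no sign of more striatal tissue in replicate 2. They went both ways and were assigned only by the nearest start site, so the dissection was not excluded. Chance stays open as well, with 5 genes in the list and 13 lists compared.

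A male sample was an unlikely source of the peaks on the Y chromosome of female tissue. In the 4 lists 0 promoter peaks of the male-specific genes Kdm5d, Eif2s3y, Uty and Ddx3y were found. Called peaks at these promoters cannot reveal a small part of male cells, so that was not excluded. Sequence shared with other chromosomes could not be settled. Of the Y peaks of both replicates 63.6% aligned elsewhere over 80% of their length at 90% identity, with 1 set of alignment settings that other settings could change, below the 80% the explanation was set to need and above the level that would exclude it.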
